A study of Mus musculus with 32 samples.

How the data were processed

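The deposited table held raw read counts per gene for 32 libraries of iMyb MyPL1 cells, with 52636 genes and 4 lines that name no gene. Per the labels' protocols, libraries were made with the QuantSeq 3′ mRNA-Seq FWD kit, so a transcript is read near its polyadenylated end and no length scaling was needed. Per the submitters' processing notes, STAR 2.4.2a and genome build GRCm38 were used. The annotation release and the strand setting of the counting are not given in the sources used here. The 4 lines that name no gene, per the file headers, are unmapped, multimapping, no-feature and ambiguous reads. They stayed out of library sizes and tests. Reads in genes made up 49.1% to 58.4% of each library's total, multimapping reads 24.7% to 29.8%, unmapped reads 6.81% to 13.0%, no-feature reads 4.88% to 9.72% and ambiguous reads 1.31% to 1.84%. Because multimapping reads were not counted, genes with near-identical copies lose reads. Without a stated strand setting, reads from overlapping or antisense genes cannot be told apart, so such genes are named as uncertain.

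Gene symbols and coordinates came from GENCODE M21 on GRCm38, matched on the Ensembl number. Of the gene IDs, 52489 matched and 147 did not. No read was counted for 31014 genes in any library. Groups were taken from the sample titles, which give day, treatment and replicate number. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. No doxycycline-treated line without the hairpin was analysed here, so the drug and the knockdown cannot be separated.

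Replicates were compared pairwise by chi-square over genes with at least 20 summed counts. The chi-square per degree of freedom ran from 5.47 to 94.5, no 2 libraries were identical, and all 32 were kept. Same-numbered libraries of a day deviated together from their group means at day 1 (r from 0.178 to 0.406), day 3 (0.139 to 0.497) and day 4 (0.149 to 0.530), over 0.1 for all 4 pairs, so the numbers were read as pairing the samples on these days. The labels give no source for the pairing. Library size, genes detected, mitochondrial share, no-feature share, multimapping share and share of the top 10 genes were compared between treated and untreated libraries of each day by exact two-sided permutation tests, and the lowest of 24 p-values was 0.0571, for the mitochondrial share at day 3. Within same-numbered pairs at day 3 the mitochondrial, multimapping and top 10 shares were higher with doxycycline in 4 of 4 pairs and the no-feature share lower in 4 of 4. At day 4 the mitochondrial and top 10 shares were higher in 4 of 4. At day 2 the multimapping share was higher and the no-feature share lower in 4 of 4. The exact two-sided sign-flip p was 0.125 for each of these, the smallest that 4 pairs can give. The unmapped share was not among the measures tested. Its means at days 1 to 4 were 10.8%, 7.94%, 8.43% and 8.56% with doxycycline and 10.6%, 10.7%, 10.5% and 9.83% without (n = 4 each). The first 4 principal components of log2 CPM held 19.3%, 17.6%, 13.5% and 6.37% of the variance, and replicate 2 had the highest mean on the second.

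Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 10441, and libraries were scaled by TMM. One quasi-likelihood model with a coefficient for each of the 8 groups was fitted to all 32 libraries (24 residual degrees of freedom, common biological coefficient of variation 0.202). Tests were treated against untreated at each day, the day 4 minus day 1 difference of these effects, the joint F test that the effect differs between days, and the F test between untreated days. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The median log2 fold change of all genes was 0.01 at day 1 and nearer 0 on the other days. CPM values are edgeR's, with TMM-scaled library totals, given as mean ± SD, and log2 fold changes as estimate ± SE. The precision depends on depth, and floors of 3 counts cover counting error only, since reads carry no molecular identifier in the table.

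Gene lists, the model, the naming rule and the alternatives were fixed before the data were examined. The lists numbered 29: MYB targets, MYC targets and ribosome biogenesis, ribosomal proteins, S phase, G2 and mitosis, cell cycle inhibitors and quiescence, pro-apoptotic BCL2 genes, anti-apoptotic genes, p53 targets, NOTCH1 pathway, early thymic progenitor, double-positive thymocyte, mature T cell, T cell receptor, T cell activation, FOXO targets, interferon response, mitochondrially encoded transcripts, ATF4 response, oxidative phosphorylation, glycolysis, cholesterol synthesis, unfolded protein response, heat shock, cytotoxic and NK, myeloid, B cell, stromal and erythroid genes. Each was tested against other genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over 116 list and day tests, and again with an estimated correlation. Fry tested whether a list moved on balance in one direction, without a comparison with other genes, and its p-values stay out of the ranges given over alternatives. With an estimated correlation 12 of 57 calls were kept. A list gene's own call was adjusted over all genes and over the list alone.

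Genes were named by rule. At day 4 these were the 12 largest rises and 12 largest falls, and at days 1 to 3 and for the day 4 minus day 1 difference the 5 largest each way. They had to be called, to average at least 10 CPM and, for single days, to have no overlap between treated and untreated libraries. Models without an established symbol were skipped. For each list the members with the lowest adjusted p at day 4, from 2 to 4 of them, were named, and for untreated cells the 3 genes with the lowest adjusted p. Other genes in the text were picked after their values were seen, as members that account for a list's count or are shared by all days.

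Alternatives were DESeq2 size factors, library size alone, no filter, a filter of 5 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, a replicate block, a fit to the compared libraries alone, and each library left out in turn. Added after the data were seen were 2 out-of-place untreated libraries left out, all untreated groups pooled, and replicate 2 left out of every group. The pooled comparison also takes in differences between the untreated days. The ends of a range over all alternatives can come from settings not named beside it, and its low end is not read as stronger evidence. The edgeR pipeline was tested on simulated counts of 10332 genes for the day 4 comparison. It recovered 16.4% of 67 genes planted at 1.5-fold, 53.7% of 67 at 2-fold and 95.5% of 66 at 4-fold. Among 112 calls 1.79% were false, with further genes planted at a smaller fold counted as true, and 0 genes were called where nothing was planted. The simulated counts were drawn independently for each library, with no pairing, day shift or out-of-place library. The false share and the 0 calls therefore do not calibrate the tests of the real data. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.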

Results

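Gene expression was measured in iMyb MyPL1 cells, a mouse T cell acute lymphoblastic leukaemia line. MyPL1 grew out of a thymic tumour from a mouse with a Myb transgene at the Rosa26 locus and Pten deleted by Lck-Cre. The iMyb derivative carries a lentiviral hairpin against Myb that doxycycline switches on, with eGFP as a reporter. Cultures received 1 µg/mL doxycycline, renewed each day, or none, and were collected at days 1, 2, 3 and 4. Each of the 8 groups held 4 libraries, 32 in all, made with a kit that sequences the 3′ ends of polyadenylated transcripts. Gene counts per library ran from 3463753 to 8862363. Levels are given in CPM, counts scaled to a common library total and corrected by TMM. In these libraries 3 counts, the upper limit that a count of 0 allows, equal 0.866 CPM before that correction at the lowest depth and 0.339 CPM at the highest. The stated purpose was to learn what MYB does in established leukaemia cells.

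Myb, the transcription factor gene targeted by the hairpin, was lower with doxycycline on every day. The gene (ENSMUSG00000019982.15) lies on the minus strand of chromosome 10 at 21124935 to 21160984 (GRCm38, GENCODE M21). At day 1 its level was 74.8 ± 30.5 CPM with doxycycline and 248 ± 25.7 CPM without (SD, n = 4 each), so that 30.2% was left. The share left was 38.8% at day 2, 41.4% at day 3 and 47.1% at day 4. At day 4 the level was 108 ± 22.6 CPM with doxycycline and 230 ± 7.45 CPM without (SD, n = 4 each). Log2 fold changes were -1.73, -1.37, -1.28 and -1.09 at days 1 to 4, with adjusted p of 1.3e-06, 1.3e-05, 1.3e-05 and 1.1e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 4 treated libraries lay below all 4 untreated ones on each day (exact two-sided permutation p = 0.0286 for each day, the smallest that 4 against 4 can give). That permutation ignored the pairing read at days 1, 3 and 4, where 4 pairs alone cannot give a p below 0.05. The effect at day 4 was not shown to differ from that at day 1 (difference 0.64 ± 0.26 SE on the log2 scale, edgeR quasi-likelihood adjusted p = 0.291). That p was adjusted over all 10441 genes, though Myb was named in advance, so it does not show an equal effect. Treated day 1 replicate 1 stood at 120 CPM, where the others of its group had 55.1 to 63.9 CPM. The counts may not cover the 3′ end of the Myb transgene, which was not tested, so they need not measure all Myb transcript.

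**Figure D1:**
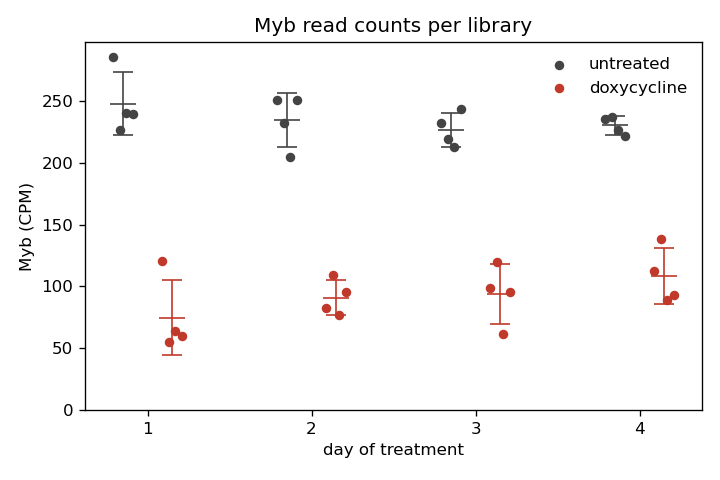
Myb level in CPM (vertical axis) against day of treatment (horizontal axis), one point per library, with the mean and SD of the 4 libraries in each group. The treated libraries lie between 55.1 and 139 CPM and the untreated ones between 205 and 285 CPM.

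After 1 day of doxycycline few genes had changed, and Myb showed the largest fall among those named. Shroom3, which encodes an actin-binding regulator of cell shape, rose from 7.41 ± 1.67 to 31.8 ± 6.35 CPM (SD, n = 4 each), a log2 fold change of 2.08 ± 0.29 (SE). Kcne4, a potassium channel subunit gene, rose by 1.40 ± 0.15, Pkdcc by 1.68 ± 0.28 and Txnip, whose product restrains thioredoxin and glucose uptake, by 1.46 ± 0.30. Mtx2 and Mcu, which encode a mitochondrial outer membrane import protein and the mitochondrial calcium uniporter, had log2 fold changes of -1.72 ± 0.23 and -1.32 ± 0.15, and Mcu overlaps another gene. Siva1, a pro-apoptotic gene, stood at -1.33 ± 0.17. Ptk7 rose by 1.38 ± 0.33, and Sema5a fell from 47.2 to 19.1 CPM, with the largest adjusted p of these genes, 0.0427. In total 65 genes passed in edgeR's quasi-likelihood test, 36 higher and 29 lower, of which 28 changed at least 2-fold. In 64 of the 65 all treated libraries lay on one side of all untreated ones, as did 7.28% of all genes tested, where chance gives 1 in 35. With the replicate number as a block 178 genes passed, 150 with no filter on low counts, 127 in DESeq2, 41 with the compared libraries alone and 251 against the untreated libraries of all days pooled. The count was 43 without treated replicate 2, 40 without untreated replicate 3 and 39 without treated replicate 3, and the calls of Ptk7 and Sema5a were lost in several runs that left out a library. For Ptk7 these were all but those without treated replicate 1 and untreated replicate 2 (adjusted p up to 0.156), and for Sema5a treated replicates 1, 2 and 3 and untreated replicates 3 and 4 (up to 0.165). Txnip was not called with the compared libraries alone (0.114) or against pooled untreated libraries (0.206, at a log2 fold change of 0.58), over all alternatives 7.3e-08 to 0.206. Ptk7 was not called there either (0.195, and 0.760 at a log2 fold change of 0.27), nor in limma-voom (0.0784) or scaled by library size alone (0.109). Sema5a was not called in that scaling or with the compared libraries alone (0.143 and 0.0568).

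At day 1 the list of cell cycle inhibitors and quiescence genes was higher than other genes (camera adjusted p = 1.6e-05, adjusted p = 0.0324 with an estimated correlation). Of its 14 measured members Cdkn1a, which encodes the inhibitor p21, passed alone, at 0.79 ± 0.18, and 4 rose when adjusted over the list alone. The S phase and DNA replication list was lower (camera adjusted p = 6.7e-06, adjusted p = 0.0499 with an estimated correlation), though none of its 30 members passed in edgeR over all genes, with 7 at an unadjusted p under 0.05, 2 called by DESeq2 and 3 when adjusted over the list alone. A further 12 lists passed with the preset correlation and not with an estimated one. Higher were FOXO targets (adjusted p = 6.7e-06, then 0.0815 with an estimated correlation), ATF4 genes (1.6e-04, then 0.266), ribosomal proteins (5.2e-04, then 0.567), p53 targets (0.00727, then 0.148), mature T cell genes (0.0167, then 0.231), early progenitor genes (0.0422, then 0.213), B cell markers (0.0488, then 0.213) and mitochondrially encoded transcripts (0.0488, then 0.482). Lower were MYC targets (7.5e-06, then 0.180 with an estimated correlation), cholesterol synthesis (8.8e-04, then 0.0980), erythroid markers (0.0198, then 0.0802) and heat shock proteins (0.0278, then 0.340). The B cell and erythroid lists held only 2 measured members each, with none called over all genes. Of 5 measured early progenitor genes Il2ra alone was called. In mean log2 CPM untreated replicate 1 was at 4.98 for ATF4 genes and -0.75 for B cell markers, the other 3 at 5.32 to 5.33 and 0.67 to 0.95. Treated replicate 3 was at 4.62 for cell cycle inhibitors and 4.65 for erythroid markers, the other 3 at 4.49 to 4.50 and 3.85 to 3.96. With the replicate block the early progenitor and B cell lists lost their calls (adjusted p = 0.0651 and 0.0820, over all alternatives 0.0176 to 0.732 and 0.00592 to 0.213). The double-positive thymocyte and glycolysis lists gained one (adjusted p = 0.0374 and 0.0419, over all alternatives 0.0374 to 0.757 and 0.0288 to 0.493). Leaving out a library ended the calls of B cell and erythroid markers (any but untreated replicate 4, adjusted p up to 0.169 and 0.192) and of mature T cell genes (untreated replicate 2, 0.0688). It also ended those of progenitor genes (untreated 1 and 3, treated 1 and 4, up to 0.116), heat shock proteins (treated 1 and 2, untreated 3 and 4, up to 0.121) and mitochondrial transcripts (treated 1 and 3, untreated 2 and 3, from 0.0550), and glycolysis passed without untreated replicate 1 (0.0332). Against the untreated libraries of all days pooled, the ATF4 and ribosomal lists turned lower and passed (adjusted p = 0.00104 and 0.00130, over all alternatives 4.8e-06 to 0.266 and 6.5e-06 to 0.567). There the cell cycle inhibitor list did not pass (0.0840, over all alternatives 4.2e-06 to 0.0840), and MYC targets, mature T cell genes, mitochondrial transcripts and heat shock proteins turned direction without passing.

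At day 2 Shroom3 reached 71.5 ± 20.8 CPM against 2.88 ± 1.15 in untreated cells (SD, n = 4 each), a log2 fold change of 4.70 ± 0.35 (SE). Mtus2 rose from 181 ± 40.7 to 597 ± 131 CPM, and Slc43a2, an amino acid transporter gene, from 19.1 ± 4.81 to 67.5 ± 13.4 CPM. Zfp703 and Kcne4 rose by 1.76 ± 0.32 and 1.75 ± 0.15. Ikzf2, which encodes the lymphoid transcription factor Helios, went from 22.7 ± 4.54 to 3.50 ± 0.614 CPM, a log2 fold change of -2.69 ± 0.38. Crhbp, Mt1, Fam183b and Acot5 also fell, with log2 fold changes from -2.57 to -2.45, and 0.00546, for Mt1, was the largest adjusted p of the genes named. In edgeR's quasi-likelihood test 430 genes passed, 238 higher and 192 lower, and 199 changed at least 2-fold. The libraries did not overlap for 407 of them, and for 10.96% of all genes tested (chance, 1 in 35). Without untreated replicate 1 the count was 277, and against pooled untreated libraries 1857, where Crhbp stood at -1.50.

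Of the 30 S phase genes at day 2, 6 fell, among them Pcna, Mcm5 and Mcm7, and 15 fell adjusted over the list alone (camera adjusted p = 3.1e-09, adjusted p = 0.0204 with an estimated correlation). Cholesterol synthesis was lower as well (adjusted p = 8.7e-07, adjusted p = 0.0235 with an estimated correlation), with Msmo1 and Cyp51, which overlaps another gene, passing of 21 members and 10 lower over the list alone. The other 11 lists that passed at day 2 lost their calls with an estimated correlation. Lower among them were ATF4 genes (1.1e-04, then 0.258 with an estimated correlation), glycolysis (0.00298, then 0.282), erythroid markers (0.0132, then 0.0659) and oxidative phosphorylation (0.0249, then 0.585). Higher were NOTCH1 targets (0.00168, then 0.213 with an estimated correlation), cell cycle inhibitors (0.0111, then 0.186), B cell markers (0.0121, then 0.119), p53 targets (0.0240, then 0.213), mature T cell genes (0.0240, then 0.260), double-positive thymocyte genes (0.0461, then 0.260) and early progenitor genes (0.0480, then 0.220). Of 2 measured B cell markers Ighm alone was called, and of 2 erythroid markers Tfrc alone. Of 5 measured early progenitor genes only Il2ra was called, and the median log2 fold change of that list was 0.0016. Leaving out a library ended the calls of erythroid markers (any but treated replicate 1, adjusted p up to 0.305), B cell markers (untreated 4, 0.0516), glycolysis (untreated 3, 0.139), mature T cell genes (untreated 1, 0.0993) and p53 targets (untreated 3 and treated 4, 0.0619 and 0.0661). It also ended those of double-positive genes (untreated 1, 2 and 4, treated 1 and 4, up to 0.118), progenitor genes (untreated 1, treated 2 and 4, up to 0.175) and oxidative phosphorylation (untreated 1 and 2, treated 4, up to 0.112). Calls were gained by ribosomal proteins (treated 1, untreated 2 and 3, down to 0.00159), MYC targets (treated 1, untreated 2, 0.00711 and 0.0361), FOXO targets (treated 1 and 2, untreated 3, down to 0.0248), T cell receptor genes (untreated 2, treated 4, 0.0471 and 0.0432) and mitochondrial transcripts (treated 1 and 3, untreated 2, up to 0.0317). The ATF4 list stood at a mean log2 CPM of 6.47 ± 0.0899 in the untreated libraries of day 2 and 5.24 ± 0.174 in those of day 1 (SD, n = 4 each). Against pooled untreated libraries the list's direction turned and it did not pass (adjusted p = 0.721, over all alternatives 1.5e-06 to 0.721).

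At day 3 the immunoglobulin mu constant region gene Ighm rose from 1.88 ± 0.863 to 23.8 ± 6.01 CPM (SD, n = 4 each), a log2 fold change of 3.73 ± 0.33 (SE). Btg1, an antiproliferative gene, rose by 2.58 ± 0.48, Pik3r3, a regulatory subunit of PI3 kinase, by 2.56 ± 0.25, and Ypel3 by 2.42 ± 0.29. Shroom3 stayed high, at 3.46 ± 0.31. Lig4, the DNA ligase of non-homologous end joining, had a log2 fold change of -2.25 ± 0.19, and Hmga1, a chromatin architectural protein gene, of -2.50 ± 0.47. Crhbp, Sema5a and Fam183b were lower as well, between -2.96 and -2.40. Hmga1 had the largest adjusted p of these genes, 3.97e-04. In edgeR's quasi-likelihood test 1077 genes passed, 650 higher and 427 lower. Scaling by library size alone gave 417 higher and 529 lower. At least 2-fold changes were found for 436 genes, the libraries did not overlap for 882 of those called and for 14.2% of all genes tested (chance, 1 in 35), and 1698 genes passed with the replicate block and 648 with the compared libraries alone.

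The S phase list was lower at day 3, with a mean log2 fold change of -0.58 and 20 of 30 members lower over all genes and 26 over the list alone (camera adjusted p = 3.5e-16, adjusted p = 0.00223 with an estimated correlation). Cell cycle inhibitors were higher, with 5 of 14 passing, Btg2, Gadd45a, Btg1, Slfn2 and Cdkn1a, and 6 adjusted over the list alone (adjusted p = 5.9e-05, adjusted p = 0.0469 with an estimated correlation). Among p53 targets 6 of 17 rose, including Bbc3, which encodes the pro-apoptotic PUMA, and as many over the list alone (adjusted p = 3.6e-05, adjusted p = 0.0337 with an estimated correlation). Treated replicate 1 stood at a mean log2 CPM of 5.34 for p53 targets, the other 3 at 4.94 to 5.00, and untreated replicate 4 at 5.07 for erythroid markers, the other 3 at 5.33 to 5.34. B cell markers (Ighm alone, adjusted p = 1.8e-04, then 0.0324) and erythroid markers (Epor and Tfrc, lower, 0.00432, then 0.0370) kept their calls too, with the same counts over the list alone. With no filter on low counts both were lost (0.131 and 0.148, over all alternatives 6.1e-08 to 0.131 and 0.00351 to 0.157). Higher with the preset correlation alone were FOXO targets (1.8e-05, then 0.0957 with an estimated correlation), double-positive genes (9.7e-04, then 0.0743), ribosomal proteins (0.00254, then 0.593), early progenitor genes (0.0198, then 0.154), mature T cell genes (0.0198, then 0.235), T cell receptor genes (0.0208, then 0.223), mitochondrial transcripts (0.0381, then 0.454, with a mitochondrial share of 5.55 ± 0.783% against 4.15 ± 0.507% of gene counts, SD, n = 4 each, exact permutation p = 0.0571, higher in 4 of 4 same-numbered pairs) and NOTCH1 targets (0.0484, then 0.412). Lower in that way were G2 and mitosis genes (2.3e-05, then 0.211 with an estimated correlation), MYC targets (7.5e-05, then 0.220), cholesterol synthesis (6.7e-04, then 0.0957), ATF4 genes (0.00181, then 0.359) and glycolysis (0.00479, then 0.312). Of 5 measured early progenitor genes Il2ra alone was called at day 3. With the replicate block NOTCH1 targets lost their call (adjusted p = 0.164, over all alternatives 0.0176 to 0.412) and MYB targets were lower (adjusted p = 0.0285, over all alternatives 0.0273 to 0.152). Leaving out a library ended the calls of erythroid markers (any but treated replicate 4, adjusted p up to 0.125), ribosomal proteins (treated 2, 0.163), progenitor genes (untreated 2, treated 4, 0.0519 and 0.0509) and mature T cell genes (untreated 1 and 2, treated 4, up to 0.0724). It also ended those of mitochondrial transcripts (untreated 1 and 3, treated 2 and 4, up to 0.0987) and NOTCH1 targets (untreated 1 and 2, treated 3 and 4, up to 0.216). Calls were gained by MYB targets (untreated 2, treated 4, 0.0353 and 0.0273), heat shock proteins (untreated 4, 0.0264) and oxidative phosphorylation (treated 2, 0.0494). Untreated day 3 replicate 4 had a mean ATF4 log2 CPM of 6.49 where the other 3 untreated libraries had 5.26 to 5.48, and without it the day 3 ATF4 call was lost (adjusted p = 0.226, over all alternatives 7.8e-06 to 0.359).

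By day 4 Ighm had risen from 2.67 ± 1.71 to 48.4 ± 16.0 CPM, Shroom3 from 3.84 ± 1.76 to 70.4 ± 17.5 CPM and Il2ra, the interleukin 2 receptor alpha chain CD25, from 1.89 ± 0.662 to 29.8 ± 8.77 CPM (SD, n = 4 each). Their log2 fold changes were 4.25 ± 0.32, 4.24 ± 0.33 and 3.91 ± 0.29 (SE). The next largest rises were Pik3r3 at 2.46 ± 0.25, Nhsl1 at 2.34 ± 0.28, Zfp703 at 2.20 ± 0.32, Rhou at 2.12 ± 0.20 and Kcne4 at 2.11 ± 0.15. Zdhhc14, Tle6, Plekho2 and Btg1 followed, between 2.06 and 1.83. The deepest falls were in the metallothionein gene Mt2, at -4.26 ± 0.64, in Trib3, a pseudokinase gene driven by ATF4, at -4.23 ± 0.58, and in Crhbp, at -4.06 ± 0.47. The metallothionein gene Mt1 stood at -3.60 ± 0.59, Cox6a2, a cytochrome c oxidase subunit gene, at -3.80 ± 0.53 and Sema5a at -3.38 ± 0.38. Cd5, an inhibitory T cell surface receptor, went from 22.9 ± 7.49 to 2.61 ± 1.26 CPM, a log2 fold change of -3.06 ± 0.40. Ikzf2, Hmga1 and Sh2d1a, the gene of the adaptor SAP, stood at -2.97 ± 0.39, -2.72 ± 0.46 and -2.62 ± 0.31. Fam183b and Cth, which encodes an enzyme of cysteine synthesis, stood at -3.22 ± 0.35 and -2.64 ± 0.37. The largest adjusted p among these 24 genes was 0.00669, for Btg1, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Untreated Mt2 and Mt1 levels varied widely at day 4, at 115 ± 129 and 117 ± 130 CPM. Without untreated day 4 replicate 3 the day 4 minus day 1 difference of effects went from -3.70 to -2.56 for Mt2. For Mt1 it went from -3.06 to -1.93, so the size of both falls depends on that library. Mt1 and Mt2 are near copies that can share reads, and Pik3r3, Rhou, Cox6a2, Hmga1 and Sh2d1a overlap other genes, so their values are uncertain. Against pooled untreated libraries Cox6a2 and Hmga1 stood at -2.48 and -1.81.

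**Figure D2:**
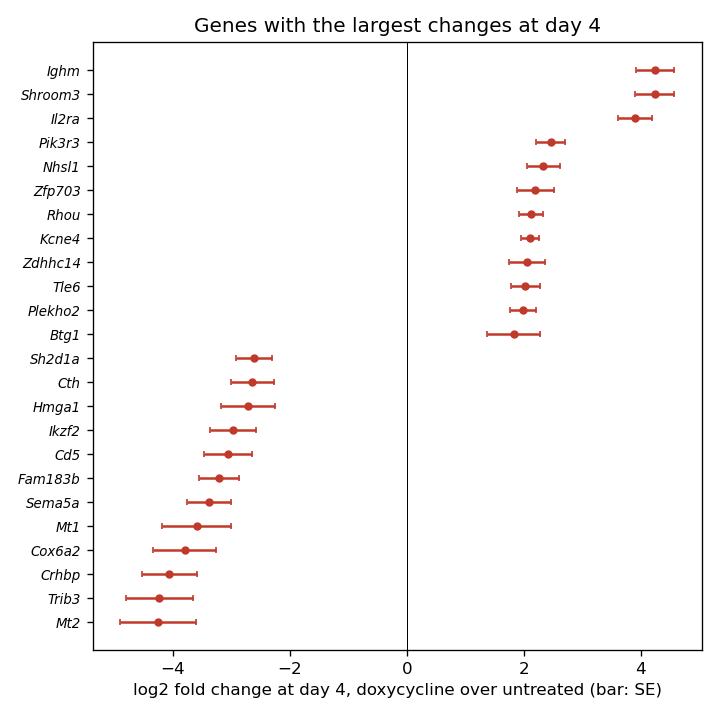
Log2 fold change at day 4, doxycycline over untreated (horizontal axis), of the 12 largest rises and 12 largest falls, with SE bars from 4 libraries per group. Ighm, Shroom3 and Il2ra lie near 4 and Mt2, Trib3 and Crhbp below -4.

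In all, 1085 genes passed at day 4, 520 higher and 565 lower, and 463 changed at least 2-fold. The libraries did not overlap for 840 of those called, and for 13.1% of all genes tested (chance, 1 in 35). Scaling by library size alone gave 359 higher and 576 lower. With the replicate number as a block 1697 genes passed, with the compared libraries alone 566 and against pooled untreated libraries 2084. With the compared libraries alone the calls below of Npm1, Rfc2, Pola1, Cd8a, Lcp2, Bad, Ccnd3, Nr4a1, Atp5h, Gpi1, Aldoa, Srebf2, Edem1 and Hsp90b1 were lost (adjusted p from 0.0514 for Cd8a to 0.178 for Edem1). Those of Npm1, Rfc2 and Edem1 were lost without the filter (0.0733, 0.0893 and 0.298), and of Ccnd3, Mvd, Srebf2 and Hsp90b1 with library size alone (0.103, 0.0693, 0.0874 and 0.103). Without replicate 4 of untreated days 3 and 4, those of Bad, Ccnd3, Atp5h, Srebf2, Edem1 and Hsp90b1 were lost (0.0528, 0.154, 0.0543, 0.102, 0.0574 and 0.0837). Without replicate 2 of every group those of Aldoa, Edem1 and Hsp90b1 were lost (0.0694, 0.0872 and 0.0992), and against pooled untreated libraries those of Klf2, Nr4a1 and Rsad2 (0.0576, 0.0506 and 0.0859). Over all alternatives of these 17 genes the lowest adjusted p ran from 1.6e-16 for Nr4a1 to 0.00882 for Hsp90b1, and the highest from 0.0514 for Cd8a to 0.298 for Edem1.

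Genes of the cell cycle were lower at day 4. Of 30 S phase and DNA replication genes 17 fell and 1 rose, Ccne1, the cyclin of S phase entry (22 and 1 adjusted over the list alone). The list was lower than other genes (camera adjusted p = 4.2e-09, adjusted p = 0.0204 with an estimated correlation). Cdc45 and Gins1, parts of the replicative helicase, stood at -0.80 ± 0.14 and -0.76 ± 0.15, and Pola1, a subunit of DNA polymerase alpha, at -0.60 ± 0.14 (log2 ± SE). Of 30 genes of G2 and mitosis 12 fell and none rose, 22 over the list alone (adjusted p = 8.1e-10, adjusted p = 0.0743 with an estimated correlation). Ect2, which directs cytokinesis, had a log2 fold change of -0.97 ± 0.16, Cenpf of -0.93 ± 0.23 and Ndc80, which attaches kinetochores to microtubules, of -0.85 ± 0.18. Cdc45, Rfc2 and Nusap1 overlap other genes on the opposite strand.

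Of 22 measured ATF4 targets, the genes of the integrated stress response and amino acid synthesis, 18 fell and 1 rose at day 4 (19 and 1 adjusted over the list alone). The mean log2 fold change was -1.27 (camera adjusted p = 2.5e-16, adjusted p = 0.0324 with an estimated correlation). Atf4 went from 257 ± 44.5 to 81.8 ± 10.7 CPM, Mthfd2, a mitochondrial folate enzyme, from 447 ± 58.9 to 156 ± 16.0 CPM, and Eif4ebp1 from 231 ± 44.0 to 108 ± 14.6 CPM (SD, n = 4 each). The gene that rose was Pycr1, of proline synthesis, by 1.56 ± 0.20 (log2 ± SE). The untreated level of this list moved between days. Its mean log2 CPM was 5.24 ± 0.174, 6.47 ± 0.0899, 5.67 ± 0.558 and 6.37 ± 0.309 in untreated cells at days 1 to 4, and 5.61 ± 0.137, 6.04 ± 0.249, 5.28 ± 0.145 and 5.16 ± 0.0956 with doxycycline (SD, n = 4 each). Trib3 in untreated cells was at 5.25, 55.6, 17.5 and 54.2 CPM, and with doxycycline at 7.92, 27.7, 4.70 and 3.05 CPM.

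**Figure D3:**
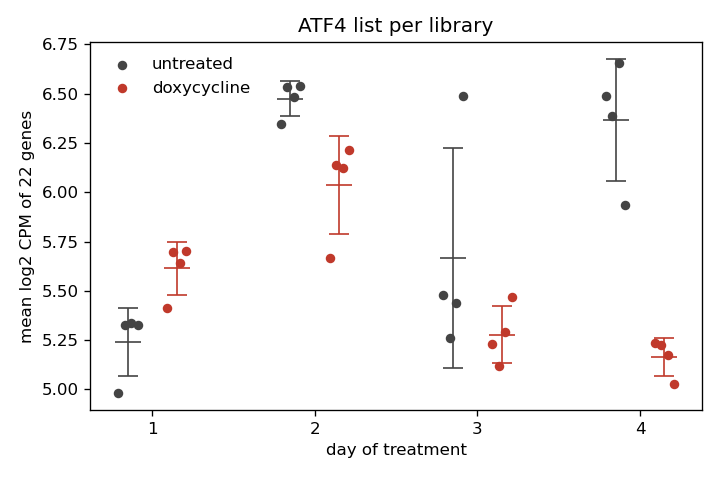
Mean log2 CPM of the 22 measured ATF4 genes (vertical axis) against day (horizontal axis), one point per library, with group mean and SD (n = 4). Untreated means were 5.24, 6.47, 5.67 and 6.37, and untreated day 3 replicate 4 stood at 6.49.

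Of 17 glycolysis genes 9 fell at day 4 and none rose, 11 over the list alone (camera adjusted p = 1.1e-04, adjusted p = 0.187 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, stood at -1.17 ± 0.31 and Gpi1 at -0.65 ± 0.17. Without untreated replicate 3 neither passed, at -0.77 and -0.38 (adjusted p = 0.124 and 0.136), nor did Aldoa and Tpi1 (0.218 and 0.0791), which overlap other genes. Aldoa then went from -0.84 to -0.43. Aldoa was also not called without treated replicate 4 (0.0654). The unfolded protein response list did not pass (adjusted p = 0.180, over all alternatives 0.0825 to 0.389), with 4 of 16 lower, among them Herpud1 at -1.38 ± 0.24 (-0.82 against pooled untreated libraries), and Dnajc3 higher at 0.74 ± 0.13 (4 and 1 over the list alone). Edem1 and Hsp90b1 fell by little, at -0.34 ± 0.11 and -0.55 ± 0.17, and lost their calls in runs without a library. For Edem1 these were all but untreated and treated replicate 3 (adjusted p up to 0.0979), for Hsp90b1 untreated 1 and 4 and treated 2 and 4 (up to 0.148). Cholesterol synthesis did not pass either (adjusted p = 0.0740), but did with no filter, in limma-voom and against pooled untreated libraries (0.0186, 0.0478 and 9.7e-04, over all alternatives 9.7e-04 to 0.359), with 2 of 21 lower and 1 higher in both ways of adjusting. These were Cyp51 at -0.66 ± 0.13, Srebf2 at -0.66 ± 0.21, and Mvd, which overlaps another gene, at 0.58 ± 0.14. Srebf2 lost its call without untreated replicates 1, 3 or 4 or treated replicates 2 or 3 (adjusted p up to 0.141).

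Of 17 p53 targets 6 rose at day 4 and none fell, in both ways of adjusting (camera adjusted p = 6.1e-04, adjusted p = 0.0659 with an estimated correlation). In mean log2 CPM of this list untreated replicate 4 stood at 4.42, where the other 3 untreated libraries had 4.69 to 4.74. Cdkn1a went from 500 ± 122 to 1133 ± 190 CPM and Btg2, an antiproliferative gene, from 70.1 ± 13.9 to 211 ± 57.4 CPM (SD, n = 4 each). Sesn1, a stress-induced inhibitor of mTORC1, rose by 1.40 ± 0.23 and the noncoding Trp53cor1 by 1.35 ± 0.32. Of 14 cell cycle inhibitors and quiescence genes 4 rose, Btg2, Cdkn1a, Btg1 and Rbl2, which overlaps another gene, and Klf2, a quiescence factor, fell, at -1.59 ± 0.32 (7 and 3 over the list alone), and stood at -0.72 against pooled untreated libraries. That list passed (adjusted p = 0.0249, adjusted p = 0.220 with an estimated correlation), but not without untreated replicate 4 (adjusted p = 0.188) or replicate 1 (adjusted p = 0.0502), over all alternatives 1.2e-04 to 0.220. Of 17 FOXO targets 4 rose, including Txnip at 1.81 ± 0.28 and Pik3ip1 at 1.23 ± 0.29, and Klf2 fell (5 and 2 over the list alone). The list passed (adjusted p = 0.0461, adjusted p = 0.412 with an estimated correlation), and leaving out a library ended the call for untreated replicates 1, 2 and 4 and treated replicates 3 and 4 (adjusted p from 0.0510 to 0.189, over all alternatives 6.5e-06 to 0.412). Of 7 anti-apoptotic genes Mcl1 and Cflar rose, by 0.73 ± 0.13 and 0.85 ± 0.16, 3 over the list alone (adjusted p = 0.0240, adjusted p = 0.208 with an estimated correlation). Without treated replicate 2 that call was lost (adjusted p = 0.0622, over all alternatives 0.0119 to 0.208). The 7 pro-apoptotic BCL2 genes did not pass as a list (adjusted p = 0.119). Bad rose alone, by 0.67 ± 0.17, with 2 higher over the list alone, and Bad, which overlaps another gene, was not called without treated replicate 2 (adjusted p = 0.0580). The list passed without untreated replicate 3 (adjusted p = 0.0497, over all alternatives 0.0497 to 0.280).

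Among T cell genes the changes at day 4 went both ways. Of 9 NOTCH1 pathway genes Il2ra and Igf1r rose, the latter from 0.985 ± 0.696 to 9.30 ± 2.86 CPM, and Ccnd3, a D-type cyclin gene that overlaps another, fell, at -0.72 ± 0.23 (3 and 2 over the list alone). Without treated replicates 1, 2 or 4 or untreated replicates 3 or 4 Ccnd3 was not called (adjusted p up to 0.158). The list passed (camera adjusted p = 0.0326, adjusted p = 0.361 with an estimated correlation), with a mean of 0.75 and a median of 0.11. The call was lost with the replicate block (adjusted p = 0.134, over all alternatives 9.7e-04 to 0.651) and without untreated replicates 1 or 2 or treated replicates 3 or 4 (adjusted p from 0.0724 to 0.137). Of 5 early progenitor genes Il2ra rose alone, in both ways of adjusting (adjusted p = 0.0208, adjusted p = 0.154 with an estimated correlation). The median of that list was -0.03, opposite in sign to its mean of 0.74, and without untreated replicate 2 it did not pass (adjusted p = 0.0737, over all alternatives 3.7e-04 to 0.586). Of 18 double-positive thymocyte genes 5 rose and 4 fell, 7 and 4 over the list alone (adjusted p = 0.101, with the replicate block 0.0268, over all alternatives 0.00777 to 0.359). Rag1, a subunit of the V(D)J recombinase, rose by 1.45 ± 0.24, Ets2 by 1.40 ± 0.20 and Cd8a by 0.52 ± 0.09, while Aqp11 stood at -2.16 ± 0.23. Of 14 mature T cell genes 4 rose and 3 fell, 5 and 4 over the list alone (adjusted p = 0.488, over all alternatives 0.0164 to 0.977), among them Itgb7 at 1.65 ± 0.19, Emb at 0.72 ± 0.10 and the class I gene H2-D1, one of a family of near copies, at -1.52 ± 0.26. Of 20 T cell receptor genes 5 rose, including Cd3e at 0.77 ± 0.12 and Lcp2 at 0.84 ± 0.16, and Cd5 and Cd6 fell, 6 and 2 over the list alone (adjusted p = 0.122). Of 12 immediate activation genes Il2ra rose and Egr1 and Nr4a1 fell, at -2.17 ± 0.54 and -2.05 ± 0.59, 2 and 5 over the list alone (adjusted p = 0.664). The Nr4a1 call was lost without treated replicates 1 or 4 or untreated replicate 3 (adjusted p = 0.0812, 0.0761 and 0.169, the last at a log2 fold change of -1.36), and the T cell receptor list passed without treated replicate 2 (0.0342, over all alternatives 0.0223 to 0.412). Rag1, Emb and Lcp2 overlap other genes.

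MYB targets did not pass as a list at day 4 (camera adjusted p = 0.0740), and did with the replicate block (adjusted p = 0.0400, over all alternatives 0.0400 to 0.184) and without treated replicate 3 (0.0437). Of 13 measured members 3 fell and none rose, in both ways of adjusting. Gata3, a T lineage transcription factor gene, went from 91.0 ± 34.2 to 28.2 ± 10.6 CPM (SD, n = 4 each), a log2 fold change of -1.67 ± 0.27 (SE). Rag2 and Gfi1 stood at -1.05 ± 0.28 and -0.59 ± 0.16, and neither passed without treated replicate 1 (adjusted p = 0.0603 and 0.0644). Myc was at 65.8 ± 27.4 CPM with doxycycline and 129 ± 13.8 CPM without, which did not pass in edgeR's quasi-likelihood test (adjusted p = 0.114). It passed with the replicate block (adjusted p = 0.0123) and without treated replicate 3 (0.0475), among other settings (over all alternatives 2.2e-06 to 0.839). Gata3 and Rag2 overlap other genes.

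Of 30 MYC targets of ribosome biogenesis Npm1 fell alone, from 2455 ± 297 to 1760 ± 124 CPM, in both ways of adjusting (day 4, camera adjusted p = 0.410, over all alternatives 7.1e-04 to 0.821). Ncl, at -0.82 ± 0.32, passed with the replicate block, among other settings (adjusted p = 0.00419, over all alternatives 6.2e-05 to 0.498). None of 40 ribosomal protein genes passed in edgeR's quasi-likelihood test or DESeq2, with 1 at an unadjusted p under 0.05 (list adjusted p = 0.225). Rps19, at 0.40 ± 0.18, passed with the block, among other settings (adjusted p = 0.0337, over all alternatives 0.00117 to 0.589). The ribosomal list passed without treated replicates 1 or 3 or untreated replicate 2 (adjusted p = 0.0383, 0.0447 and 0.00592, over all alternatives 1.7e-04 to 0.990). None of 8 heat shock genes passed in edgeR or DESeq2, with 0 at an unadjusted p under 0.05 (list adjusted p = 0.573). Of 28 oxidative phosphorylation genes Atp5h rose over all genes and none over the list alone (list adjusted p = 0.855). The Atp5h call was lost without untreated replicates 1, 3 or 4 or treated replicate 2 (adjusted p up to 0.124). Of 8 mitochondrially encoded transcripts mt-Cytb rose, from 1995 ± 293 to 3562 ± 576 CPM, in both ways of adjusting (list adjusted p = 0.262, over all alternatives 0.00495 to 0.660). Mitochondrial transcripts made up 6.77 ± 1.05% of gene counts with doxycycline and 5.54 ± 1.04% without (SD, n = 4 each), higher in 4 of 4 same-numbered pairs. Of 12 interferon response genes Psmb9, Tap1, Psmb8 and Rsad2 fell and Lgals3bp rose, in both ways of adjusting (list adjusted p = 0.0962, without untreated replicate 4 0.0233, over all alternatives 0.0223 to 0.771). The mean of that list was -0.52. Psmb9 and Tap1 overlap each other. With the replicate block, among other settings, Bmf, Bcl2l1 and Nr4a2 also passed (adjusted p = 0.0387, 0.0416 and 0.0191, over all alternatives 1.6e-05 to 0.219, 0.0359 to 0.422 and 0.0143 to 0.385). Bmf and Nr4a2 did so without untreated replicate 3 as well (0.00560 and 0.0415).

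Markers of other cell types were mostly too low to test. Of 14 B cell markers 2 were measured, Ighm, which rose, and Vpreb1, at 1.75 ± 0.610 CPM with doxycycline and 1.11 ± 0.872 CPM without (camera adjusted p = 6.7e-06, adjusted p = 0.0163 with an estimated correlation). With no filter on low counts that call was lost (adjusted p = 0.259, over all alternatives 7.2e-12 to 0.259). Of 10 erythroid markers Tfrc and Epor were measured, and Epor fell, from 2.17 ± 0.504 to 0.288 ± 0.349 CPM. The erythroid list passed (adjusted p = 0.0381, adjusted p = 0.119 with an estimated correlation), but not with the replicate block (adjusted p = 0.0555, over all alternatives 0.0186 to 0.473) or in any run that left out a library (0.217 to 0.406). Of 4 measured cytotoxic and NK genes Cd160 rose, by 1.03 ± 0.17, and Il2rb fell, from 2.74 ± 1.99 to 0.134 ± 0.268 CPM, with reads in treated replicate 3 alone (list adjusted p = 0.783, with a mean of -0.84 but a higher direction in the test). That list passed with the stricter filter and with the compared libraries alone (adjusted p = 0.0256 and 0.0345, over all alternatives 0.0256 to 0.990), as it did at day 3 (0.0358 and 0.0234, over all alternatives 0.0234 to 0.883). Itgam, the measured myeloid marker, and Pecam1, the measured stromal marker, did not pass in edgeR or DESeq2, nor at an unadjusted p under 0.05 (list adjusted p = 0.739 and 0.599). Vpreb1, Cd160 and Itgam overlap other genes. The counts for these 5 lists were alike over the list alone.

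**Figure D4:**
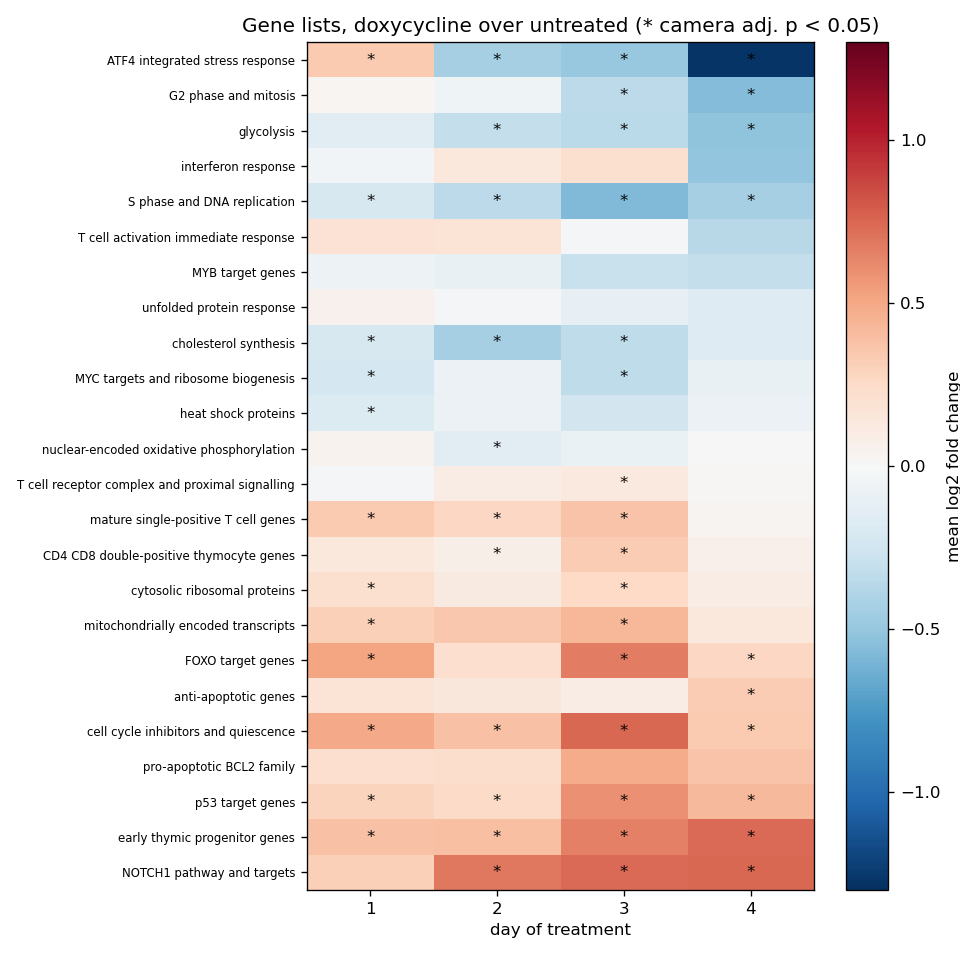
Mean log2 fold change, doxycycline over untreated (colour), of 24 gene lists (vertical axis) at each day (horizontal axis), with an asterisk where the list passed in camera with the preset correlation. The ATF4 list is at -1.27 and the S phase list at -0.44 at day 4.

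Most genes called at days 1 and 2 were called in the same direction on each later day, from 72.4% to 96.6% of the rises or falls. Of the rises and falls of day 3, 53.4% and 58.3% were called at day 4. Days 3 and 4 shared 347 rises and 249 falls, where independent lists would share 32.4 and 23.1, and no gene was called in opposite directions. Of the 65 genes of day 1, 29 rises and 28 falls were also called at day 4 (1.79 and 1.57 by independent lists, Fisher's exact test p = 4.7e-32 and 4.9e-35). That test takes genes as independent, which they are not, so its p-values do not measure the spread between samples. On all 4 days 28 genes rose, among them Il2ra, Shroom3, Kcne4 and Cdkn1a, and 26 fell, among them Myb, Gata3, Ikzf2, Lig4, Mcu and Mtx2. Across genes, which are not independent replicates, log2 fold changes of days 3 and 4 correlated with r = 0.719 and those of days 1 and 4 with r = 0.351. Each day had its own untreated libraries.

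Whether the effect of doxycycline changed with time was tested directly. The effect on Ighm was larger at day 4 than at day 1 by 2.95 ± 0.49 on the log2 scale (SE), that on Shroom3 by 2.16 ± 0.44 and that on Pik3r3 by 1.56 ± 0.35. Ifngr1, the interferon gamma receptor, and Dgka, a diacylglycerol kinase, followed at 1.26 ± 0.26 and 1.22 ± 0.28. Trib3 showed the largest difference the other way, at -4.78 ± 0.80, followed by Cox6a2 at -3.97 ± 0.72, Mt2 at -3.70 ± 0.84, Crhbp at -3.25 ± 0.63 and Mt1 at -3.06 ± 0.78. A difference of effects also takes in any shift of the untreated level between the days, as given for Trib3 with the ATF4 genes. In edgeR's quasi-likelihood test 99 genes differed between days 4 and 1, 30 towards higher and 69 towards lower, and 97 had the effect further from 0 at day 4. Over all 4 days jointly 32 genes passed, and 122 with the replicate block. The joint count moved by over 1.5 times in 9 of the runs that left out a library, from 5 without treated day 4 replicate 1 to 64 without untreated day 3 replicate 4, as listed with the processing alternatives. Calls were lost for Pik3r3 (without untreated day 4 replicate 1, untreated day 1 replicate 3, treated day 1 replicate 4 or treated day 4 replicate 4, adjusted p up to 0.0619). Those of Dgka, which overlaps Pmel, were lost without treated day 4 replicate 1, untreated day 1 replicates 3 or 4 or treated day 1 replicate 4 (up to 0.0769). Mt2 lost its call without untreated day 1 replicate 1, treated day 4 replicate 1, untreated day 4 replicate 3 or treated day 1 replicate 4 (up to 0.0948), and stood at -2.56 without untreated day 4 replicate 3. Mt1 lost it in all runs but those without untreated day 4 replicates 1 or 4 (up to 0.199), and stood at -1.93 without untreated day 4 replicate 3. With limma-voom Cox6a2, Mt2, Crhbp and Mt1 were not called (0.0653, 0.135, 0.0536 and 0.185), nor were Dgka and Mt1 with library size alone (0.0604 and 0.0802) or Pik3r3, Mt2 and Mt1 without replicate 2 of every group (0.0953, 0.0995 and 0.150). Over all alternatives the lowest adjusted p of these 6 genes ran from 2.4e-42 for Cox6a2 to 0.00404 for Pik3r3. For Cox6a2 edgeR's quasi-likelihood test with all libraries gave an adjusted p of 0.00309. The low end thus depends strongly on the setting and does not measure the evidence.

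Untreated cells also differed between days. Akap12, which encodes a scaffold for protein kinase A, was at 34.2 ± 5.85, 5.62 ± 0.998, 28.4 ± 11.8 and 10.9 ± 3.84 CPM at days 1 to 4 (SD, n = 4 each). Sft2d2 was at 15.2, 36.2, 24.0 and 39.1 CPM and Snrpa1, a U2 snRNP gene that overlaps another gene, at 146, 82.1, 137 and 84.6 CPM. Of 22 ATF4 genes 17 differed between the untreated days. Of the genes called for doxycycline at day 4, 220 also differed between untreated days. Among these, 121 fell with doxycycline and were higher in untreated cells at days 2 and 4 than at days 1 and 3. Another 45 rose with doxycycline and were lower in untreated cells at days 2 and 4. In all, 1102 genes passed in edgeR's quasi-likelihood test of the 4 untreated groups. The count was 717 without day 1 replicate 4 and reached 1511 without day 3 replicate 4.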

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

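The screens for libraries apart from their group and for effects that differ between days were set before the data were examined, as were the splits of the samples. The tests on the untreated ATF4 level, mitochondrial translation, the place and depth of untreated day 3 replicate 4, B cells and the difference between synthetase sets were chosen only after the result was seen. The tRNA synthetase lists were chosen after the ATF4 result was seen, though their test values were not yet known.

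The ATF4 list was lower with doxycycline at day 4 and its effect differed from day 1 by -1.61 on the log2 scale (camera adjusted p = 1.3e-31, adjusted p = 0.00250 with an estimated correlation). An action of doxycycline on mitochondrial translation is a stress known to raise ATF4 targets. At day 4 the mean log2 fold change was -1.27, with treated libraries at 5.03 to 5.24 and untreated ones at 5.93 to 6.66 in mean log2 CPM. That direction is opposite to such a stress, but the test restated the fall already seen and cannot decide the cause. At day 1 the list was higher with doxycycline (mean 0.339, camera adjusted p = 1.6e-04, adjusted p = 0.266 with an estimated correlation). Against the untreated libraries of all days pooled it was lower at day 1, a comparison that also takes in differences between the untreated days. ATF4-driven tRNA synthetase genes passed too (camera adjusted p = 4.0e-15 over 12 tests), and others did not (camera adjusted p = 0.256), which alone excludes no fall. At day 4 a fall by the same amount is argued against by a difference of -0.71 between the sets' changes (exact permutation p = 0.0286, with the pairing ignored). Both changes had been seen when that test was chosen. It compares with untreated day 4 cells alone, so it cannot separate a fall with doxycycline from a raised untreated level. A raised untreated level at day 4 stays open as well, because its test, 4 of the 18 members that fell being also lower than in untreated day 1 cells (15 for day 2 and 12 for day 3), restated group means already seen. An effect of the knockdown on ATF4 signalling remains open and cannot be separated from other actions of the drug.

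Untreated day 3 replicate 4 stood apart from its group in mean log2 CPM of erythroid markers, at 5.07 where the others were at 5.33 to 5.34, while its 6.49 for ATF4 genes, beside 5.26 to 5.48, fell short of the limit of that screen. A depth effect is argued against by its 5326180 gene counts, inside the range of the other untreated libraries. On 586 genes that differ between untreated days 3 and 4 in replicates 1 to 3, scaled to 0 for day 3 and 1 for day 4, it lay at 0.698 and untreated day 4 replicate 4 at 0.353. An exchange of these libraries and a single library of another day therefore cannot be told apart from spread between samples, because both positions fall between the bounds set for each. No biological explanation was tested.

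Ighm rose more at day 4 than at day 1, by 2.95 (edgeR quasi-likelihood adjusted p = 0.00167), and the list of B cell markers by 1.80 (camera adjusted p = 0.00583, adjusted p = 0.0863 with an estimated correlation). B cells in the culture are argued against, since Cd79a, Cd79b and Cd74 together reached 0.266% of the Ighm CPM in treated day 4 libraries, with 0 reads of Cd79a and Cd79b against 1019 of Ighm. Transcription of the locus within the leukaemia cells is a hypothesis that stays open and was not tested.

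Other effects that differed between days 4 and 1 in edgeR's quasi-likelihood test were Shroom3 at 2.16, Pik3r3 at 1.56, Ifngr1 at 1.26, Dgka at 1.22, Trib3 at -4.78, Cox6a2 at -3.97, Mt2 at -3.70, Crhbp at -3.25 and Mt1 at -3.06. Among lists S phase differed by -0.23, G2 and mitosis by -0.59 and glycolysis by -0.39 (camera adjusted p = 0.00776, 1.1e-11 and 0.0143, and 0.414, 0.0863 and 0.578 with an estimated correlation). Jointly over the days 32 genes differed. All these differences include any shift of the untreated level between the days.

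Of 112 groups of 4 libraries tested, 9 had a library far from the other 3, where chance gives about 1 in 20. Treated day 1 replicate 1 had 120 CPM of Myb, the other 3 having 55.1 to 63.9 CPM. Untreated day 1 replicate 1 was low in mean log2 CPM of G2 and mitosis genes at 5.84, of ATF4 genes at 4.98 and of B cell markers at -0.75. Treated day 1 replicate 3 was high for cell cycle inhibitors at 4.62 and for erythroid markers at 4.65. For p53 targets untreated day 4 replicate 4 was low at 4.42 and treated day 3 replicate 1 high at 5.34.

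With the pairing ignored, a random split was excluded for the count of each day over all 35 splits of its libraries. The real split alone gave as many genes, with 65, 430, 1077 and 1085 genes at days 1 to 4 and 10, 1, 111 and 421 in the highest other split. The splits with 111 and 421 genes each exchanged treated replicate 2 with untreated replicate 4 of their day. The replicate numbers were read as pairing the samples at days 1, 3 and 4, where 8 splits part all 4 pairs, too few for a share under 0.05. With the pairing kept, chance is therefore not excluded on those days by the splits. Of these 8 splits the real one gave 65, 1077 and 1085 genes and the highest other 0, 0 and 25. At day 2 a pairing was not excluded, and if the numbers pair the samples the same limit holds there. Among its 8 such splits the real one gave 430 genes and the highest other 1. For the joint test of the effect over days, 2 of 100 draws gave as many genes as the real 32, itself included. The other gave 275, several times the real count, and had all day 4 labels reversed but most labels of days 2 and 3 in place, a structure that sets the doxycycline effect in opposite directions. A random labelling that ignores the pairing is excluded by that share. The draws also removed effects common to all days, so they did not test equal effects. For untreated days 1 of 100 draws, the real one with 1102 genes, was as large, and the highest other gave 676.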

How the results depend on the processing

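The runs with pooled untreated groups, without replicate 2 and without 2 untreated libraries were chosen only after the result was seen. DESeq2 size factors in edgeR changed no call among 166 named gene values and 116 list tests. Across other settings gene calls were lost for 8 values (library size alone), 3 (no filter), 5 (limma-voom), 17 (compared libraries alone), 6 (2 untreated libraries out), 5 (pooled untreated groups) and 6 (replicate 2 out), and no called gene changed sign. DESeq2 lost none. Values under the threshold in both fits changed sign in 7 of 3110 gene and 51 of 2262 list comparisons, fry included, and count as kept. Gene calls were gained for 10 values against pooled untreated groups, 6 with the block, 4 with no filter and at most 1 elsewhere. List calls were lost in 45 tests with an estimated correlation, 23 with no filter, 10 with replicate 2 out and at most 7 under other settings, apart from pooled untreated groups. There 6 were lost with the direction kept and 7 tests turned direction. List calls were gained in 16 tests against pooled groups, 6 with the block, 6 with the compared libraries alone, 5 with no filter, 4 with the stricter filter and 2 each with library size alone, limma-voom, 2 untreated libraries out and replicate 2 out. Fry, which compares a list with no change and not with other genes, passed 9 tests that camera did not and missed 12 that camera passed. Without the filter the B cell, erythroid and early progenitor lists were lost on all 4 days, and the mature T cell and NOTCH1 lists on each of the 3 days they had passed. At this depth, spread and number of libraries 16.4% of simulated 1.5-fold changes were recovered, and the part of depth alone was not tested. The causes of the changes below were not tested, with these exceptions. Fits to the compared libraries or without a library hold fewer samples. The comparison with pooled untreated groups sets treated cells of 1 day against untreated cells of all days and so takes in day differences. Such differences were called for 1102 genes in untreated cells, so its counts and turned directions do not measure doxycycline alone.

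At day 1 the 65 genes became 43 with library size alone, 150 with no filter, 127 with DESeq2, 41 with the compared libraries alone and 251 against pooled untreated groups. At day 2 the 430 became 1857 against pooled groups. At day 3 the 1077 became 648 with the compared libraries alone, and at day 4 the 1085 became 566, and 2084 against pooled groups. Without both out-of-place untreated libraries 1216 and 1007 passed at days 3 and 4, of which 907 and 871 were among the original calls, and the day 3 ATF4 list lost its call (0.256). The joint test over days went from 32 to 213 with no filter, 96 with DESeq2, 20 with limma-voom and 2 without replicate 2. Untreated days went from 1102 to 507 with the compared libraries alone. The 596 genes shared by days 3 and 4 became 326 at an adjusted p below 0.01 and 314 with each day fitted alone. List calls went from 57 to 12 with an estimated correlation.

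With the replicate number as a block 178, 802, 1698 and 1697 genes passed at days 1 to 4, including all original calls, 122 in the joint test and 2257 between untreated days. At day 2 the numbers were not read as pairing the samples (r from 0.0470 to 0.314, 2 of 4 over 0.1). There 1 of 4 libraries was closest to its own number, beside 3, 4 and 3 of 4 at days 1, 3 and 4. A pairing at day 2 is not excluded, since its lowest r was positive and the block raised its count from 430 to 802. On that day the block ended the early progenitor call (0.0679) and added ribosomal proteins (0.0499). Beyond these and the calls given with the results, it changed no call of a named gene or list.

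Of the 7 list tests that turned direction against pooled untreated groups, only ribosomal proteins and ATF4 genes at day 1 passed there. At day 1 these were MYC targets (adjusted p 0.543), ribosomal proteins (0.00130), mature T cell genes (0.982), mitochondrial transcripts (0.998), ATF4 genes (0.00104) and heat shock proteins (0.600), and at day 2 ATF4 genes (0.721).

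Leaving out each library in turn gave 39 to 91 genes at day 1, 277 to 400 at day 2, 763 to 1167 at day 3, 806 to 1012 at day 4, 5 to 64 in the joint test and 717 to 1511 between untreated days. The joint count moved by over 1.5 times without untreated day 1 replicates 2 (21) and 3 (14), treated day 1 replicates 2 (21) and 4 (11), untreated day 3 replicate 4 (64), untreated day 4 replicates 1 (18) and 4 (60), and treated day 4 replicates 1 (5) and 3 (19). Calls changed at least once for 22 of 166 gene values and 41 of 116 list tests.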

Other observations

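The tRNA synthetase and lysosomal lists and the count of alternating genes were chosen only after the data had been seen, with the list tests not yet run when their outcomes were set down, while the test between the synthetase sets came after. For the lysosomal list the rise of Lipa had been seen.

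Genes that charge transfer RNAs with amino acids divided at day 4 by whether ATF4 is known to drive them. Of 12 ATF4-driven cytosolic synthetase genes 10 fell and none rose, with a mean log2 fold change of -0.88 (camera adjusted p = 4.0e-15 over 12 tests, adjusted p = 0.0128 with an estimated correlation). Nars stood at -1.05 ± 0.16 and Gars at -0.60 ± 0.11 (SE). Of 8 other synthetase genes none passed in edgeR's quasi-likelihood test or DESeq2, with 1 at an unadjusted p under 0.05 (mean -0.15, camera adjusted p = 0.256). Mean log2 CPM of the driven set minus that of the other was -0.94 ± 0.0241 with doxycycline and -0.23 ± 0.183 without (SD, n = 4 each, exact two-sided permutation p = 0.0286, the smallest possible, with the pairing ignored). The ATF4-driven set had 3 and 6 members lower at days 2 and 3, and 0 at day 1 in edgeR, DESeq2 or at an unadjusted p under 0.05.

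Lysosomal genes were higher at days 3 and 4. At day 4, 7 of 21 rose and none fell (camera adjusted p = 1.5e-04, adjusted p = 0.0182 with an estimated correlation), among them Lipa, the lysosomal acid lipase, at 1.53 ± 0.19, Lamp1 at 0.37 ± 0.10 and Ctsd at 0.43 ± 0.13 (SE). At day 3, 8 rose and Lamp2 fell (camera adjusted p = 1.3e-04, adjusted p = 0.0182 with an estimated correlation). At day 1 none passed in edgeR's quasi-likelihood test or DESeq2, with 5 at an unadjusted p under 0.05 (camera adjusted p = 0.0214, adjusted p = 0.120 with an estimated correlation), and at day 2 Ctsb rose and Lamp2 fell (camera adjusted p = 0.191). A hypothesis, set from the rise of Lipa and tested on the same data, is that lysosomal genes may rise as a group, and the day 4 list test went with it.

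Untreated cells alternated between the days. Of the 1102 genes that differed between untreated days, 520 were higher at both days 2 and 4 than at days 1 and 3, and 483 were lower, together 91.0%. Among the 9339 genes not called 55.2% had such an order. That share is not a chance level, because genes that were not called can alternate too.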
